A study of Mus musculus with 12 samples.

How the data were processed

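RNA was extracted from muscle of control mice and of IRMOE mice, which overexpress the insulin receptor in skeletal muscle, and was sequenced as 12 RNA-seq libraries on an Illumina NextSeq instrument, per the labels. The titles and the treatment label put 6 samples in the control group and 6 in the IRMOE group. The muscle that was sampled, the age of the animals and their diet are not given in the sources used here. The submitters' processing notes name the aligner STAR, the read counter featureCounts and the genome build GRCm38.p6, with no versions or settings. The strand setting and the annotation release are not given in the sources used here.

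The processed data used here consist of 1 deposited table of whole-number read counts per gene, with Ensembl gene identifiers as rows and 12 columns of values. Each column is headed by a code. None of the codes (0 of 12) occurs in a title, description, characteristic or protocol of the 12 samples, and apart from the title, the accession and the treatment the samples carry identical labels. A column was to be given a sample only where its name matched that sample's labels. Neither the order of the columns nor the counts themselves were used to assign columns. An assignment made from the count of the insulin receptor gene would also have fixed the outcome of the comparison for that gene. The 12 columns of per-sample values were therefore not used, and no depth per library, expression level, fold change or test is given.

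The planned analysis had been fixed before the data were examined. It consisted of a quasi-likelihood test of IRMOE against control over all genes, the insulin receptor gene as a check of the labels, tests of 32 gene lists and the shares of the adult myosin heavy chains. Of these comparisons, 0 were run. Of the lists, 22 held pathways or functions and 10 held markers of cell types that muscle can contain.

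What was computed from the table concerns its row identifiers alone. These were compared with the GENCODE M21 annotation of mouse (GRCm38) by gene identifier without its version, using Python 3.11.15. Symbols of the fixed lists were looked up in that annotation, also under newer symbols, and each was counted as having a row where its identifier occurred in the table. Coordinates are 1-based GRCm38 positions from GENCODE M21. No statistical test was made. The match was repeated with the reference chromosomes alone and with a table of gene names, and the list lookup without the newer symbols.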

Results

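The study measured gene expression in mouse muscle by RNA-seq. Of the 12 samples, 6 came from control mice and 6 from IRMOE mice. In IRMOE mice a transgene that carries the cDNA of mouse insulin receptor isoform A is driven by the CAG promoter, a strong promoter active in most tissues. A floxed stop cassette blocks the transgene until Cre recombinase removes it. Cre was expressed here from the human skeletal muscle actin promoter, which is meant to restrict removal to skeletal muscle fibres. Where the cassette was removed was not examined here. The comparison that the design implies is IRMOE against control, and the series title places it in the context of glucose intolerance caused by diet and of insulin resistance beyond the receptor.

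That comparison was not made. The 12 columns of counts carry codes that match none of the sample labels (0 of 12 matched). Columns were assigned by label names alone, so no library was given to a group. No gene is reported here as higher or lower in IRMOE muscle, and nothing is reported as unchanged.

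The table listed 54547 distinct gene identifiers. Of these, 53706 (98.46%) were found in GENCODE M21 and 841 were not. Among the 53620 identifiers placed on the reference chromosomes, 21890 were annotated as protein-coding genes, 9147 as processed pseudogenes and 5340 as long intergenic non-coding RNAs. These numbers describe which genes could receive counts, not which were expressed.

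The gene that the transgene carries, Insr (ENSMUSG00000005534), encodes the insulin receptor and had 1 row in the table. It is a protein-coding gene on the minus strand of chromosome 8 of GRCm38, from 3122061 to 3279617, a span of 157557 bp. Its longest annotated protein-coding transcript, Insr-201, has 21 exons. A shorter protein-coding transcript, Insr-203, is annotated with 5 exons from 3174795 to 3192717 and so covers only part of the span of Insr-201. Insr-203 contains an internal exon of 36 bp at 3181702 to 3181737 on chromosome 8 that Insr-201 skips. The receptor's isoforms A and B differ by skipping or inclusion of 1 such short exon, with isoform A lacking it. A count per gene holds no information on that exon, and it does not separate reads of a mouse Insr cDNA transgene from those of the endogenous gene.

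The rows covered the genes of the planned comparison. All 34 genes of the list for insulin signalling downstream of the receptor had a row. This list includes Irs1 and Irs2, the adaptor proteins that the receptor phosphorylates, and Akt2, the kinase through which insulin acts on glucose uptake. The same held for all 24 negative regulators of insulin signalling, such as Grb10 and Ptpn1, and for all 20 genes of glucose uptake and glycogen metabolism, among them Slc2a4, the insulin-responsive glucose transporter. All 18 glycolysis genes, 13 slow-twitch fibre genes and 16 fast-twitch fibre genes had rows as well. Over the 32 lists together, 561 of 561 genes had a row. Of the 55450 GENCODE M21 genes on the reference chromosomes, 53620 had one. A full or nearly full count for the lists could therefore be foreseen and is no finding about them. Having a row says nothing about whether a gene was detected in any library.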

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

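No paired analysis was possible because the columns of the count table carry codes and no replicate numbers. The numbers in the sample titles are not tied by any label to a shared litter, batch or day, so they would not by themselves pair control and IRMOE samples. Other normalizations, other filters on low counts, other test tools, a replicate block and leaving out each library were not run, since the comparison they vary was not made. The checks of the row identifiers were chosen after seeing the data. Of the 54547 identifiers, 53706 were found in GENCODE M21 with its scaffolds, and 53620 with the reference chromosomes alone or with the table of gene names. The reference chromosomes hold 55450 of the 55536 GENCODE M21 genes, so the counts with and without scaffolds could differ only slightly. All 561 genes of the fixed lists had a row with and without the newer symbols. What depth limits was not assessed.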
